A study of Homo sapiens with 4 samples.

How the data were processed

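The series holds 4 libraries of guide RNA cassettes amplified by PCR from genomic DNA of OCI-AML5 cells that carry Cas9 and the EKO knockout library. Per the labels, cells were infected with an HMGA2-YFP or a YFP vector for 3 days, given 2 ug/mL doxycycline for 7 days and expanded for 7 days, in DMEM with 10% serum and 10 ng/ml GM-CSF. The labels do not place day 0 before or after doxycycline, and name no replicates. The deposited values are raw counts of reads per guide, with no normalization. The submitters' processing notes name bcl2fastq 2.20, Trim Galore, Bowtie2 2.3.3 and MAGeCK without their settings, so the mismatches allowed are unknown. All columns of values were used. Depth ran from 13848918 to 27087435 counts per library. PCR reads without molecular identifiers are not independent molecules.

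Of 233268 guides, 200161 target 18921 genes, 30773 target 10821 exons that are named by coordinates, 2043 are non-targeting controls and 291 target 26 names that a spreadsheet had turned into dates. The date-like names cannot be told back to genes and were not tested as genes. The exon targets carry no genome build, so they were not assigned to genes. Their own changes are given in the closing section only. Gene names are those of the file. Of the tested names, 17441 are current symbols in the RefSeq table of assembly GRCh38.p14, 1262 are older symbols there and 82 are absent, and that table was used for names, chromosomes and neighbours alone.

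A guide was measured if the day 0 libraries held at least 20 counts of it together, which kept 232380 guides. A gene was tested with at least 4 measured guides, which left 18785 genes with 4 to 27 guides and a median of 10, and left out 136. Counts were divided by size factors (median of ratios over all guides), a pseudocount of 5 was added, and log2 ratios were taken between the libraries of 5 comparisons. Within 50 bins of day 0 abundance, guides were ranked by log2 ratio and given normal scores. The size factors, bins, ranks and the random sets below used all measured guides, including those against exons, date-like names and no gene. The statistic of a gene was the mean score of its guides. Its two-sided permutation p came from 1000000 random sets of as many guides, for which 1e-06 is the smallest value possible, and was adjusted by Benjamini-Hochberg over all genes tested at a threshold of 0.05. With 1 library per group no comparison had replicates from which to take the spread between samples, so this test compares libraries and not conditions. The values printed are means over guides of the log2 ratio with standard errors over guides.

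Before the data were examined, 27 gene lists, 6 genes to report whatever their value (HMGA2, HMGA1, CSF2RA, CSF2RB, JAK2 and 1 not named here), the tests and most alternatives were fixed. The named genes rule was, per comparison, the 15 lowest and 10 highest mean log2 changes among genes past the threshold, those 6 genes, and up to 4 members per list, 2 at each end. Where no gene passed, the 5 lowest and 5 highest mean scores were to be named and said not to pass. Some genes that this rule selects are left unnamed and 2 of the lists are not described, although all entered the tests and counts. Members of the lists outside that rule are named where a list had few calls, after their values were seen. The lists hold 1178 different measured genes, of which 4 stand in more than 1 list. List medians were placed among 10000 random lists matched on day 0 abundance in 10 bins. The same gene test was run on 203 made-up genes of 10 non-targeting guides each.

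The method was tested on simulated data, in which 200 genes were changed in the HMGA2 day 7 library and 18585 were not. All simulated libraries started from day 0 abundance, with a spread beyond counting taken from non-targeting guides. In the difference of changes it called 100% of genes lowered by 2 on the log2 scale, 68.0% of those lowered by 1, 8.00% of those lowered by 0.5, 88.0% of those raised by 1, and 9 unchanged genes. For HMGA2 over time those shares were 100%, 98.0%, 26.0% and 100%, with 11 unchanged genes called.

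Alternatives were scaling on total counts or on non-targeting guides, a pseudocount of 1 or 20, no count filter or at least 100 counts, no abundance bins, robust rank aggregation, leaving out the farthest guide, a null of non-targeting guides, at least 8 guides, a threshold of 0.01, the median of guides for lists, and for the difference the distance from a fitted line and the day 7 libraries alone. Added after seeing the data were nulls of olfactory receptor guides and of guides of depleted genes, another draw of random sets, and control scaling for list medians. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.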

Results

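Guide RNA abundance was measured in 4 sequencing libraries from a pooled CRISPR knockout screen in OCI-AML5, an established human acute myeloid leukaemia cell line that was grown with the cytokine GM-CSF. The cells carried Cas9 and the EKO knockout library, and either a vector expressing HMGA2, a chromatin architecture protein of embryonic and some malignant cells, with YFP, or a control vector with YFP alone. Each vector was sampled at day 0 and at day 7, with 1 library per group, so no value below has replicates. Errors given with gene values are standard errors over the guides against that gene, and n counts those guides. Guides are separate reagents within 1 culture, so the tests compare these libraries and cannot say how replicate cultures would vary. The total count was 27087435 in HMGA2 day 0, 22117066 in HMGA2 day 7, 23324815 in YFP day 0 and 13848918 in YFP day 7. The median count per guide in the same order was 103, 80, 89 and 50. Of 233268 guides, 108, 870, 118 and 1105 had a count of 0.

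Knockouts are called depleted or enriched where the mean score of a gene's guides passed a Benjamini-Hochberg adjusted two-sided permutation p of 0.05 over the 18785 genes tested. Every change is a log2 ratio relative to the median guide of the library. Guides that target no gene ended above that median, with a median log2 change of 0.41 in YFP and 0.40 in HMGA2 over 2035 guides, so an enriched knockout is one that outpaced the library and not one shown to outgrow unedited cells. Scaling on those guides moved the median of all genes by -0.41 in YFP and by -0.37 in HMGA2. Guides against olfactory receptors, which cut genes that blood cells do not use, had medians of 0.20 and 0.19 over 3578 guides.

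**Figure D1:**
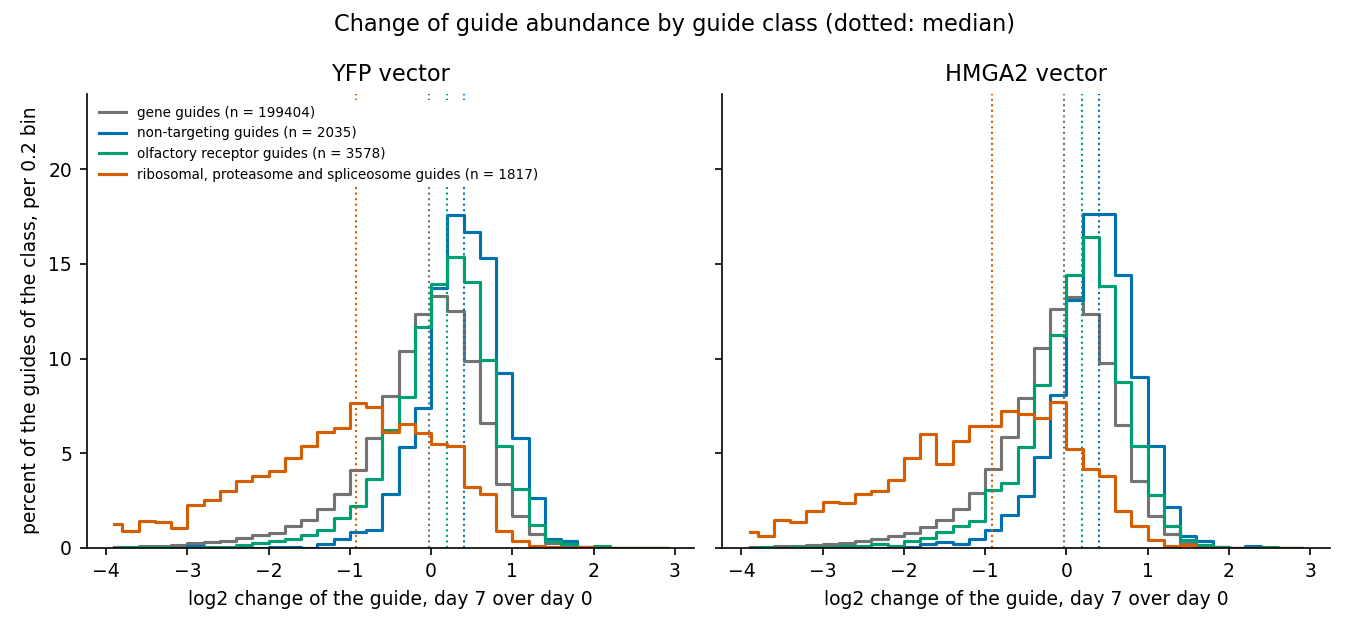
Share of guides of each class, in percent per bin, against the log2 change of the guide from day 0 to day 7, with YFP on the left and HMGA2 on the right. Dotted lines are class medians, and guides beyond the axis are counted in the outermost bin. Guides against ribosomal, proteasome and spliceosome genes sit lowest, with medians of -0.93 and -0.92, and non-targeting guides sit highest, with medians of 0.41 and 0.40 relative to the library median.

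With the YFP control vector, the comparison of day 7 with day 0 asked which knockouts these cells lost or kept over 7 days. The deepest loss among genes past the threshold was of SPI1, which encodes the myeloid transcription factor PU.1, at -2.30 ± 0.22 (n = 10). ATP6V0C, a subunit of the proton pump of lysosomes, stood at -2.15 ± 0.32 (n = 10). PFAS, an enzyme of purine synthesis, followed at -2.11 ± 0.45 (n = 10), and TYMS, which makes thymidylate, at -2.07 ± 0.31 (n = 13). In all, 1036 knockouts were depleted and 153 enriched.

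Of the 15 lowest knockouts a further 10 were TBCC, ATP6V1A, IMP3, IARS, NDC80, AQR, LAS1L, TRIM28, RPL30 and RPAP1, between -2.11 and -1.97, and 1 is not named here. Each of those named had an adjusted permutation p of 0.000139 and at least 9 guides that pointed down. TRIM28 is a corepressor of repeats and zinc finger targets.

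Core cell machinery was depleted across several lists. Among cytosolic ribosomal proteins, 59 of 72 measured members were depleted (67 adjusted over the list alone), with a list median of -1.27. In the spliceosome core, 32 of 48 were depleted (38 adjusted over the list alone), led by the helicase AQR at -2.02 ± 0.42 (n = 10) and SF3B3 at -1.95 ± 0.33 (n = 10). DNA replication lost 29 of 47 (36 adjusted over the list alone), including the ribonucleotide reductase subunit RRM1 at -1.94 ± 0.34 (n = 11) and the licensing factor CDT1 at -1.87 ± 0.28 (n = 10). Cytosolic tRNA synthetases lost 16 of 23 (19 adjusted over the list alone), with IARS at -2.04 ± 0.48 (n = 10), while the scaffold proteins AIMP1 and AIMP2 of the synthetase complex had values of 0.30 and 0.24 and did not pass. For the proteasome the count was 16 of 32 (21 adjusted over the list alone), with PSMB4 at -1.47 ± 0.31 (n = 11), whereas the catalytic subunit PSMB5 had a value of 0.20 ± 0.19 (n = 10) and did not pass. RNA polymerase II and its general factors lost 20 of 43 (32 adjusted over the list alone), among them CDK9, the kinase of transcription elongation, at -1.61 ± 0.36 (n = 10). Mitochondrial ribosomal proteins lost 9 of 73 (24 adjusted over the list alone) around a median of -0.46. Complex I of the respiratory chain lost 2 of 45 (2 adjusted over the list alone), NDUFAB1 and NDUFA13, around a median of -0.22.

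Mitotic genes were lost across several lists. Of the kinetochore and spindle list, 21 of 42 were depleted (30 adjusted over the list alone), with the kinetochore protein NDC80 at -2.03 ± 0.36 (n = 10) and the spindle motor KIF11 at -1.82 ± 0.17 (n = 10). Cohesin and condensin lost 12 of 21 (16 adjusted over the list alone), with the protease ESPL1 that cleaves cohesin at -1.54 ± 0.30 (n = 10). The G2/M list lost 14 of 40 (19 adjusted over the list alone), with BUB3 at -1.69 ± 0.28 (n = 10) and CCNA2, encoding cyclin A2, at -1.43 ± 0.23 (n = 10). The anaphase promoting complex lost 8 of 19 (10 adjusted over the list alone), with CDC16 at -1.85 ± 0.30 (n = 10). In G1/S control, 2 of 20 were depleted (2 adjusted over the list alone), the kinase CDK6 at -1.34 ± 0.24 (n = 10) and its partner CCND2 at -1.12 ± 0.27 (n = 10). In homologous recombination and the Fanconi pathway, 6 of 29 were depleted (8 adjusted over the list alone), with RAD51C at -1.54 ± 0.43 (n = 10) and XRCC3 at -1.49 ± 0.32 (n = 10).

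Myeloid factors and cytokine signalling were lost in part. Among haematopoietic transcription factors, 10 of 34 were depleted (16 adjusted over the list alone). Besides SPI1 these included IRF8 at -1.68 ± 0.19 (n = 9), MYB at -1.65 ± 0.35 (n = 9), and LYL1, LDB1 and LMO2 between -1.25 and -1.15. Of the GM-CSF signalling list, 5 of 22 were depleted (6 adjusted over the list alone). They were the receptor chains CSF2RB, at -1.58 ± 0.34 (n = 10), and CSF2RA, at -0.98 ± 0.28 (n = 20), the adaptor SHC1, the RAS exchange factor SOS1, at -1.62 ± 0.36 (n = 10), and MYC. The receptor kinase JAK2 had a value of -0.65 ± 0.25 (n = 10) and did not pass over all genes, with an adjusted permutation p of 0.165, or 0.0382 over the 6 genes fixed in advance. Without the farthest guide CSF2RA missed the threshold over all genes, with an adjusted permutation p of 0.0505, and JAK2 that over the 6 genes, with 0.177. The random sets drop no farthest guide, so such values, here and below, are weaker in part by construction. Negative regulators of cytokine and RAS signalling had a list median of 0.12, and 4 of 24 were enriched (5 adjusted over the list alone). NF1, which switches RAS off, had a change of 0.40 ± 0.17 (n = 15), SPRED2 of 0.48 ± 0.10 (n = 12), the phosphatase PTPN1 of 0.47 ± 0.20 (n = 12) and LZTR1 of 0.48 ± 0.19 (n = 10). With scaling on non-targeting guides the median of this list turned to -0.29 and NF1 to -0.01. SPRED2, PTPN1 and LZTR1 stayed just above 0 with that scaling, at 0.055, 0.047 and 0.06.

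Lists of cell death and growth signalling had few members past the threshold. Of the anti-apoptotic list, 2 of 9 were depleted (2 adjusted over the list alone), BCL2 at -1.91 ± 0.38 (n = 10) and MCL1 at -0.95 ± 0.39 (n = 10). Of the pro-apoptotic list, 0 of 15 passed (0 adjusted over the list alone). Positive members of mTOR signalling lost 2 of 22 (3 adjusted over the list alone), RPTOR at -1.18 ± 0.29 (n = 10) and MTOR at -0.91 ± 0.29 (n = 10). Negative regulators of PI3K and mTOR also lost 2 of 11 (2 adjusted over the list alone), TSC2 at -1.03 ± 0.26 (n = 10) and STK11 at -0.90 ± 0.18 (n = 11), 2 genes known as brakes on growth. Chromatin regulators lost 10 of 54 (14 adjusted over the list alone), with the arginine methyltransferases PRMT5 at -1.66 ± 0.37 (n = 10) and PRMT1 at -1.54 ± 0.33 (n = 11) lowest. In the HMGA2 and let-7 list, 0 of 15 passed (2 depleted adjusted over the list alone). HMGA2 had a value of 0.02 ± 0.12 (n = 10) and its relative HMGA1 one of -0.29 ± 0.25 (n = 11).

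Among the 10 highest enriched knockouts were CXorf22, CYLC1, PCDH11X, OVCH1, ZNF735, VAMP3, ZNF845, OR4C46 and PDHA1, between 0.64 and 0.72, and 1 is not named here. PDHA1 encodes a subunit of pyruvate dehydrogenase, and CYLC1 a protein of sperm. Olfactory receptors had a median of 0.15, with 10 of 358 enriched (4 adjusted over the list alone), and factors of other tissues had a median of 0.05, with 1 of 46 enriched (0 adjusted over the list alone). Both medians were negative, at -0.27 and -0.36, with scaling on non-targeting guides.

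Made-up genes of 10 non-targeting guides were called enriched in 52 of 203 cases and depleted in 0, so enrichment calls include what happens to uncut cells. Against a null of non-targeting guides 4 knockouts were enriched, PDHA1, CYLC1, OVCH1 and PCDH11X, and the call of ZNF845 was lost without its farthest guide.

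With the HMGA2 vector, the same comparison over time asked which knockouts were lost when HMGA2 was expressed. CDC16, a subunit of the anaphase promoting complex, had the deepest loss past the threshold, at -2.39 ± 0.33 (n = 10). LRR1 stood at -2.34 ± 0.24 (n = 11), the Integrator subunit INTS3 at -2.28 ± 0.35 (n = 10), and RCC1, the exchange factor for the nuclear transport GTPase RAN, at -2.23 ± 0.44 (n = 10). BCL2, which blocks apoptosis, was also among the lowest at -2.06 ± 0.39 (n = 10). The counts were 1019 depleted and 165 enriched.

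RAD9A, NARS, SF3B3, KIF11, DYNC1H1, RPL30, NDNL2, RPL3 and VARS were also among the 15 lowest, between -2.15 and -1.97, and 1 is not named here. Each of those named had an adjusted permutation p of 0.000157. RAD9A belongs to the clamp that signals DNA damage, and NDNL2 to the SMC5/6 complex.

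Machinery lists were depleted with HMGA2 as well. Ribosomal proteins lost 58 of 72 (65 adjusted over the list alone) around a median of -1.26, and the spliceosome core 29 of 48 (40 adjusted over the list alone), with SF3B3 at -2.05 ± 0.34 (n = 10) and PRPF19 at -1.66 ± 0.32 (n = 10). DNA replication lost 30 of 47 (36 adjusted over the list alone), with CDC45 at -1.81 ± 0.23 (n = 10), and tRNA synthetases 17 of 23 (19 adjusted over the list alone), with NARS at -2.09 ± 0.29 (n = 11). The proteasome lost 14 of 32 (21 adjusted over the list alone), with PSMD2 at -1.67 ± 0.24 (n = 11), and RNA polymerase II with its factors 18 of 43 (29 adjusted over the list alone), with POLR2I at -1.87 ± 0.30 (n = 11). Mitochondrial ribosomal proteins lost 7 of 73 (13 adjusted over the list alone), and complex I 4 of 45 (5 adjusted over the list alone), NDUFAB1, NDUFA13, NDUFB8 and NDUFB10. The median of complex I was -0.11 with HMGA2, and the median difference between vectors was 0.07, inside the range of random lists.

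Mitosis and repair lists gave similar counts. The kinetochore and spindle list lost 18 of 42 (29 adjusted over the list alone), with KIF11 at -2.02 ± 0.24 (n = 10) and TUBGCP2, a subunit of the microtubule nucleating ring, at -1.87 ± 0.30 (n = 10). Cohesin and condensin lost 10 of 21 (17 adjusted over the list alone), the G2/M list 15 of 40 (21 adjusted over the list alone) and the anaphase promoting complex 9 of 19 (12 adjusted over the list alone). In G1/S control CCND2, at -1.32 ± 0.27 (n = 10), and CDK6, at -1.25 ± 0.21 (n = 10), were the 2 of 20 depleted (4 adjusted over the list alone). Homologous recombination and the Fanconi pathway lost 6 of 29 (12 adjusted over the list alone), with XRCC3 at -1.48 ± 0.34 (n = 10).

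Of haematopoietic transcription factors, 12 of 34 were depleted (15 adjusted over the list alone), with IRF8 at -1.57 ± 0.30 (n = 9) and SPI1 at -1.38 ± 0.29 (n = 10) lowest. The GM-CSF list lost 5 of 22 (8 depleted and 1 enriched adjusted over the list alone), which were CSF2RB at -1.62 ± 0.37 (n = 10), SOS1 at -1.41 ± 0.36 (n = 10), MYC, CSF2RA at -0.88 ± 0.23 (n = 20) and the transcription factor STAT5B. JAK2 had a value of -0.69 ± 0.26 (n = 10) with an adjusted permutation p of 0.184 over all genes and 0.0279 over the 6 genes fixed in advance, or 0.12 over these without its farthest guide. Negative regulators of cytokine and RAS signalling had a median of 0.14 (-0.24 with scaling on non-targeting guides) and 0 of 24 past the threshold (0 adjusted over the list alone).

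BCL2 and MCL1 were the 2 of 9 anti-apoptotic genes depleted (2 depleted and 1 enriched adjusted over the list alone). CYCS, encoding cytochrome c, which also carries electrons in respiration, was the 1 of 15 pro-apoptotic genes depleted (1 adjusted over the list alone), at -0.91 ± 0.37 (n = 12). That list had a median of 0.02 in YFP and 0.08 in HMGA2 but a negative mean in both, and the medians turned to -0.39 and -0.30 with scaling on non-targeting guides. RPTOR and WDR24 were the 2 of 22 positive mTOR members depleted (2 adjusted over the list alone), and STK11 and TSC2 again the 2 of 11 negative regulators (2 adjusted over the list alone). Chromatin regulators lost 10 of 54 (12 depleted and 1 enriched adjusted over the list alone), and EED, a subunit of Polycomb repressive complex PRC2, was enriched at 0.50 ± 0.16 (n = 12). The HMGA2 and let-7 list lost 2 of 15 (2 adjusted over the list alone), the microRNA processing genes DICER1 at -0.98 ± 0.36 (n = 10) and DGCR8 at -0.82 ± 0.08 (n = 10). Both also had a mean change below 0 with YFP, and neither passed in the difference between vectors, even over the list alone. HMGA2 had a value of -0.57 ± 0.20 (n = 10) with an adjusted permutation p of 0.176 over all genes and 0.0279 over the 6 genes fixed in advance, and HMGA1 one of -0.35 ± 0.27 (n = 11). Without the farthest guide the value of HMGA2 was -0.43 ± 0.17, with a permutation p of 0.0871 before adjustment.

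The 10 highest enriched knockouts were CXorf27, TAS2R1, TMEM253, DEFB104A, DIRC1, SP140L, PCDH11X, CYP39A1, DEFB116 and CXorf57, between 0.66 and 0.78. TAS2R1 encodes a bitter taste receptor, and DEFB104A and DEFB116 encode defensins. Olfactory receptors had a median of 0.12 (-0.25 with scaling on non-targeting guides), with 11 of 358 enriched (1 adjusted over the list alone), and factors of other tissues a median of 0.02 (-0.35 with that scaling and -0.03 with scaling on total counts), with 0 of 46 past the threshold (0 adjusted over the list alone).

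Made-up genes of non-targeting guides were called enriched in 46 of 203 cases. Against a null of those guides 4 knockouts were enriched, SP140L, CXorf27, PCDH11X and DIRC1, and the calls of DEFB104A and DEFB116 were lost without the farthest guide.

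**Figure D2:**
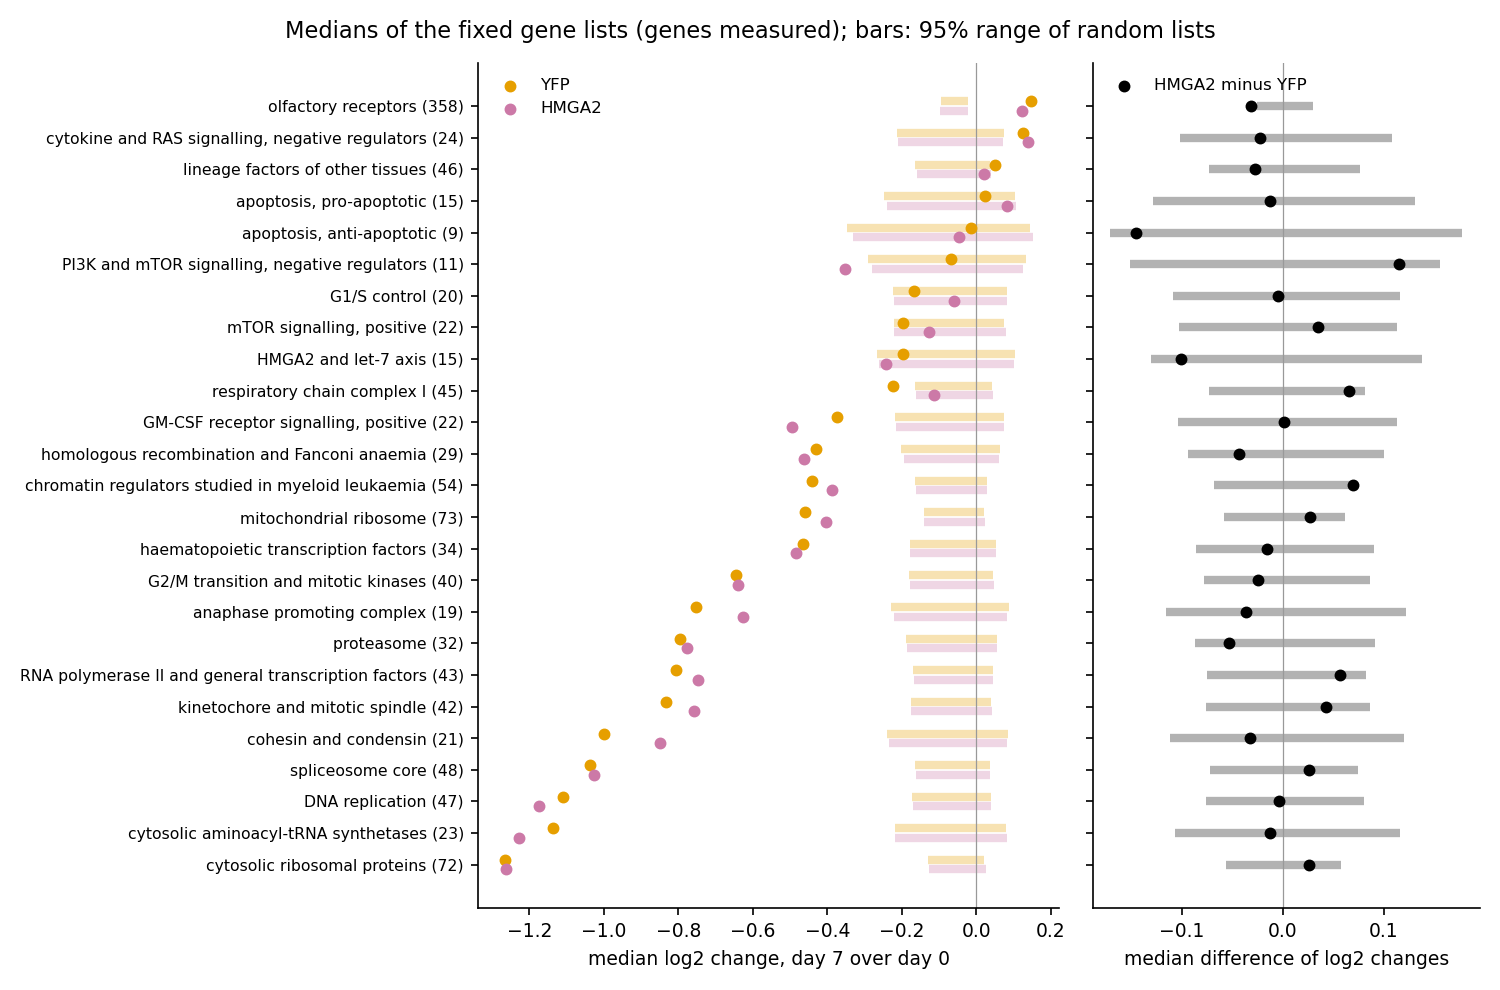
Medians of 25 of the 27 fixed gene lists, with measured members in brackets, as log2 change from day 0 to day 7 for YFP and HMGA2 on the left and as the difference of those changes on the right. Bars span the middle 95% of medians of random lists matched on abundance. Ribosomal proteins are lowest with both vectors, at -1.27 and -1.26, and the highest medians, which are above 0 here, turn negative when scaled on non-targeting guides.

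Set side by side, the vectors gave largely shared losses. Of the knockouts depleted with either vector, 775 were depleted with both, against 56.2 for independent lists. The 261 past the threshold with YFP alone and the 244 with HMGA2 alone all had a mean change below 0 with the other vector. Across genes, which are not independent replicates, the changes correlated with a Pearson r of 0.825 and a Spearman rho of 0.714, and the r was 0.671 across the 17202 genes called with neither vector. The vectors share no sequencing library but carry the same guides. Effects of a guide or its site apart from the gene can therefore add to the correlations and overlaps. Enriched knockouts overlapped less, at 15 genes against 1.34 for independent lists, and among the shared ones were GNA13, MLF2, VAMP3 and PCDH11X. GNA13, a G protein subunit, and MLF2 were picked from these 15 after their values were seen, with changes of 0.64 and 0.57 for GNA13 and 0.60 and 0.57 for MLF2.

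**Figure D3:**
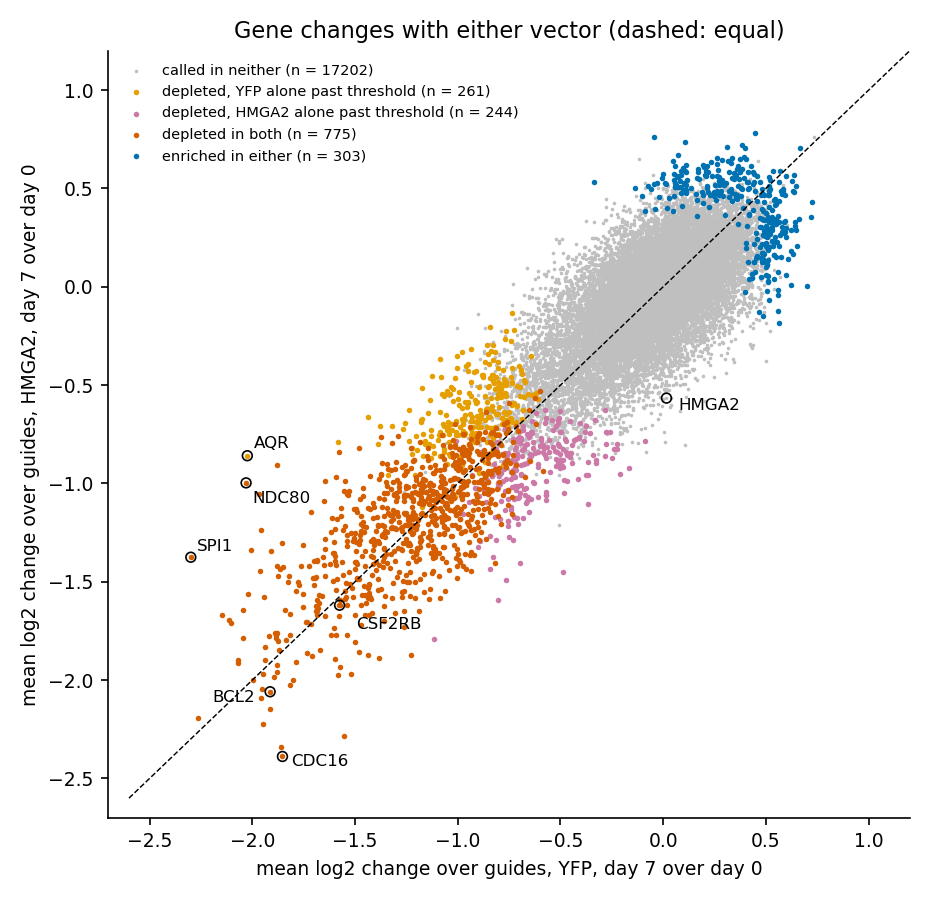
Mean log2 change of each gene over its guides from day 0 to day 7, with YFP on the horizontal and HMGA2 on the vertical axis. Each point is 1 of 18785 genes, coloured by call, and the dashed line marks equal change. The 775 genes depleted with both vectors follow the line, while AQR, NDC80 and SPI1 lie above it and HMGA2 below it, though none of these passed the test of the difference over all genes.

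The change with HMGA2 minus the change with YFP addressed whether HMGA2 altered which knockouts were lost. The gene with the strongest prior claim, HMGA2 itself, had a difference of -0.58 ± 0.18 (n = 10), from 0.02 with YFP to -0.57 with HMGA2, and 9 of its 10 guides were lower with HMGA2. Its permutation p was 0.00123, which gave an adjusted permutation p of 0.00737 over the 6 genes fixed in advance and of 0.659 over all genes. Without the farthest guide the difference was -0.46 ± 0.15, with an adjusted permutation p of 0.145 over the 6 genes. At that unadjusted permutation p or below stood 35 genes, where chance gives 23.1. Over all genes 0 knockouts passed in either direction.

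The highest scores, none past the threshold, belonged to AQR at 1.16 ± 0.37, NDC80 at 1.03 ± 0.27, SPI1 at 0.92 ± 0.30, RPAP1 at 0.92 ± 0.30 and PANX2 at 0.76 ± 0.24 (n = 10 each). Of these, AQR, NDC80, SPI1 and RPAP1 were among the 15 lowest knockouts with YFP. The lowest scores belonged to the lectin gene GRIFIN at -0.65 ± 0.23 (n = 5), SPRR2E at -0.87 ± 0.30 (n = 4), the splicing protein PNN at -0.96 ± 0.24 (n = 10), ZNF431 at -0.91 ± 0.31 (n = 9) and RBM28, of the nucleolus, at -0.79 ± 0.17 (n = 10). The smallest adjusted permutation p was 0.0939, for AQR. Of the other genes fixed in advance, 1 is not named here, and the rest had differences of 0.10 ± 0.14 for CSF2RA, -0.04 ± 0.34 for CSF2RB, -0.05 ± 0.17 for JAK2 and -0.06 ± 0.22 for HMGA1, each with an adjusted permutation p of 0.96 over the 6 genes.

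No list member passed over all genes. By chance, the null of all guides would give a member past the threshold over the list alone in 1.35 lists. That may be too low for lists rich in depleted knockouts, which more often had a low permutation p under that null, as given below. Adjusted over the list alone, 9 of 1182 members passed, in 7 of 27 lists. These were AQR of the spliceosome, YARS of the tRNA synthetases, TRIM28 of a list not described here, ANAPC5 of the anaphase promoting complex, NDC80, HAUS8 and TUBGCP2 of the kinetochore and spindle list, SPI1 of the transcription factors and HMGA2 of its own list. The counts adjusted over the list alone were 1 lower and 2 higher for the kinetochore and spindle list, 1 lower for the HMGA2 and let-7 list, 1 higher for each of the other 5 lists named, and 0 for the other 20. List medians lay between -0.15 for anti-apoptotic genes and 0.12 for negative regulators of PI3K and mTOR, a list with a negative mean. The median of 1 list, olfactory receptors, left the random range, at -0.03, beside -0.02 for non-targeting guides.

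An unadjusted permutation p under 0.05 was found for 996 genes, or 5.30%, with 491 lower and 505 higher, where chance gives 5%. Among the 1280 knockouts depleted with either vector, 173 had such a permutation p, and 78, or 6.09%, against a null of guides of depleted genes. Guides of ribosomal, proteasome and spliceosome genes spread more in this difference, with an SD of 0.84 against 0.63 for non-targeting guides, and against that null AQR had an adjusted permutation p of 0.249, the smallest of 1280 genes. AQR, NDC80 and SPI1 passed with a pseudocount of 1, at an adjusted permutation p of 0.0313, and AQR also with a minimum of 100 counts, at 0.0374. A small pseudocount gives guides with low counts larger changes. No gene passed with a pseudocount of 20, with robust rank aggregation or without the farthest guide.

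**Figure D4:**
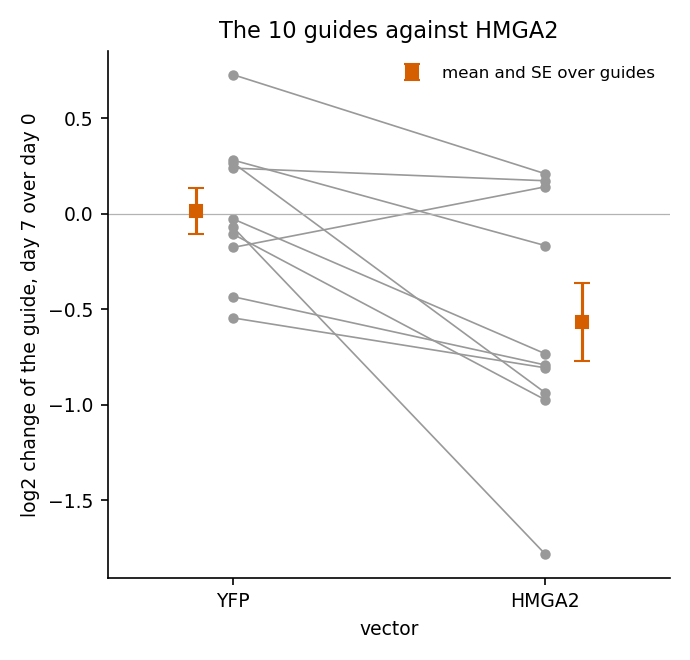
Log2 change from day 0 to day 7 of the 10 guides against HMGA2, with YFP on the left and HMGA2 on the right. Grey lines join the values of 1 guide, and squares with bars give the mean and standard error over guides, 0.02 ± 0.12 with YFP and -0.57 ± 0.20 with HMGA2. For 9 of the 10 guides the HMGA2 value is lower.

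The end points at day 7, HMGA2 against YFP, were compared without the day 0 libraries. PNN, a protein of spliced RNA complexes, was lower with HMGA2 at -1.08 ± 0.30 (n = 10), and SEC22B, which acts in transport between the endoplasmic reticulum and the Golgi, at -0.96 ± 0.31 (n = 10), both with an adjusted permutation p of 0.047. These were the 2 depleted knockouts, 0 were enriched, and 9 of 10 guides of each pointed down. HMGA2 had a value of -0.54 ± 0.20 (n = 10), with an adjusted permutation p of 0.73 over all genes and 0.0142 over the 6 genes fixed in advance, or 0.191 over these without its farthest guide. SPI1 had a value of 0.98 ± 0.26 (n = 10) and an adjusted permutation p of 0.0564. CSF2RA, CSF2RB, JAK2 and HMGA1 lay between -0.11 and 0.16, and 0 members of the fixed lists passed over all genes. Adjusted over the list alone, the lists of ribosomal proteins, RNA polymerase II and HMGA2 with let-7 had 1 lower member each, the spliceosome, tRNA synthetases, complex I, the list of TRIM28, the anaphase promoting complex and haematopoietic transcription factors 1 higher member each, the G2/M list 1 of either kind, and the kinetochore and spindle list 1 lower and 2 higher. Negative regulators of cytokine and RAS signalling had a median of -0.13, at percentile 0.42 of random lists, and olfactory receptors one of -0.03, at percentile 0.98. In the difference of changes the former list had a median of -0.02, at percentile 32.5. Both calls rested on 5e-06, an unadjusted permutation p of a few random sets, and both were lost with another draw of those sets. Neither PNN nor SEC22B passed the test of the difference of changes, at an adjusted permutation p of 0.372 and 0.477.

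At day 0 the cultures differed little. The libraries with either vector gave 0 depleted and 0 enriched knockouts, and 939 genes had an unadjusted permutation p under 0.05, 436 lower and 503 higher, where chance gives 5% of those tested. HMGA2 had a value of 0.04 ± 0.06 (n = 10). The lowest scores, not past the threshold, were those of DCAF12L2, CDH5 and CMC2, between -0.43 and -0.38, beside 2 not named here, and the highest those of MIR205HG, TRMT5, GADD45B, HSBP1L1 and UNC79, between 0.26 and 0.36. The smallest adjusted permutation p was 0.554. CSF2RA, CSF2RB, JAK2 and HMGA1 lay between -0.07 and 0.06. The proteasome, at a median of -0.05 and percentile 1.64 of random lists, was the 1 of 27 lists outside the random range. Adjusted over the list alone, the GM-CSF list had 1 lower and 1 higher member, cohesin and condensin 1 higher, and the other lists 0. Guides of ribosomal, proteasome and spliceosome genes were not scarce at day 0, with a median count of 110 in HMGA2 and 97 in YFP beside 103 and 88 for all gene guides.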

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

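Tests of the HMGA2 guides, of sequence composition for X-linked genes and of counting depth were chosen after the result was seen, and the null of guides of depleted genes was added then too.

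In 9 genes the change with HMGA2 differed from that with YFP when the permutation p was adjusted over the gene's own list, though none passed over all genes. The difference was 1.16 for AQR (1.164 before rounding), 0.72 for YARS (0.719), 0.67 for TRIM28 (0.672), 0.66 for ANAPC5 (0.662), 1.03 for NDC80 (1.033), 0.53 for HAUS8 (0.532), 0.92 for SPI1 (0.924), -0.64 for TUBGCP2 (-0.641) and -0.58 for HMGA2 (-0.582). All but HMGA2 were depleted with YFP, HMGA2 or both, and 7 of those 8 were lost less with HMGA2, TUBGCP2 being lost more. The genes were picked by this difference, which contains the YFP change with a minus sign, so their direction is no separate result. Over all genes, 491 were lower and 505 higher at an unadjusted permutation p under 0.05. Against a null of guides of depleted genes the unadjusted permutation p of these 8 ran from 0.00024 for AQR to 0.00917 for YARS, and 0 of 1280 genes passed after adjustment.

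The HMGA2 knockout had a lower change over time in the library that carried the HMGA2 vector, by -0.58 ± 0.18 relative to YFP over 10 guides. A lone outlying guide does not make up all of it, since without the lowest guide the difference was -0.456 (SE 0.149) with a permutation p of 0.0242, the highest over the settings in which it was computed, which leave out robust rank aggregation and the null of guides of depleted genes. Chance spread of guides stays open: the adjusted permutation p over the 6 genes fixed in advance was 0.00737, but 0.145 without that guide, and 0.659 over all genes. The random sets drop no guide, so the value of 0.145 is higher in part by construction. Guides against HMGA2 may also cut the integrated vector, and taking off the cost of cutting a gene at its own sites, -0.21 for olfactory receptor guides against non-targeting guides, left -0.37 ± 0.18. That cost is not the cost of added cuts in vector copies, whose number is unknown, so such cuts cannot be told apart from an effect of the knockout. A need for the introduced HMGA2 in these cells is the biological explanation that stays open with it, untested in replicate cultures and in a vector that guides cannot cut.

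X-linked knockouts sat above autosomal ones over time, at a median of 0.15 in YFP and 0.14 in HMGA2 over 750 genes against -0.07 in both over 17924, and they made up 26 of 153 and 25 of 165 enriched calls. Fewer essential genes on X would leave the upper end alone, but the 90th percentile was higher by 0.149 in YFP and 0.171 in HMGA2. Sequence composition stays open, since the file gives no guide sequences, and the 3 autosomes that X exceeded by 0.12 in both vectors were picked by their medians. Fewer DNA cuts where a site is present once is a candidate explanation. Exon targets, whose guides were not used to find the pattern, were higher on X by 0.146 in YFP and 0.128 in HMGA2. They were not assigned to genes and may lie in the same genes, so they do not separate this explanation from sequence composition. In addition, 15 pseudoautosomal genes lay below other X genes by -0.186 (SE 0.089) and -0.272 (SE 0.074). No group of the design gives a biological explanation to test, and enriched calls on X, CYLC1, PCDH11X and PDHA1 among them, carry this shift.

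No knockout passed the test of the difference between vectors over all genes. Read depth alone does not make up the spread. Poisson counting of reads gave 25% of the variance of non-targeting guides in the difference, 24.7% for gene guides and 23.8% for guides of depleted genes. PCR reads are not independent molecules, so these shares leave out the sampling of cells and DNA molecules, which was not measured and stays open. A uniform loss of 2-fold was called in 68.0% of simulated genes, which leaves open whether such a loss would have been missed, and a uniform gain of 2-fold in 88.0%. The simulation lost no gene with YFP and took its spread from non-targeting guides. Their SD in the difference was 0.63, against 0.71 for gene guides and 0.84 for ribosomal, proteasome and spliceosome guides. The simulated shares may thus be too high, above all for depleted knockouts. A loss of 0.5 on the log2 scale was called in 8% of simulated genes, so smaller differences could exist unseen in these libraries. A true absence of difference stays open beside these.

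Exon targets, which were not tested as genes, were low more often than olfactory receptor guides. Of 30650 guides, 18.4% in YFP and 15.5% in HMGA2 fell below the 5th percentile of non-targeting guides, beside 5.01% of non-targeting guides and 15.5% and 13.8% of olfactory receptor guides. Guides against genes were that low more often still, at 27.4% in YFP and 23.8% in HMGA2. All 3 guides were that low for 158 of 9230 exon targets in YFP (1.71%) and 109 in HMGA2 (1.18%). Of 1192 triplets of olfactory receptor guides, 6 and 5 were that low. Those triplets were drawn at random across genes, while the guides of a target cut 1 exon. Effects of position in the genome can thus add to the exon counts. The vectors shared 42 of the exon targets with all 3 guides low, where independent lists would share 1.87, and the guides are the same with both vectors.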

How the results depend on the processing

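The nulls of olfactory receptor guides and of guides of depleted genes, another draw of random sets and control scaling of list medians were chosen after seeing the data. Of 146 recomputed counts of calls, 110 stayed within 1.5 times the main count and 36 did not. Over time, depleted counts (1036 in YFP, 1019 in HMGA2) ran from 792 to 1043 under both scalings, both pseudocounts, the other count filters, no bins, robust rank aggregation, at least 8 guides and another draw. Leaving out the farthest guide gave 565 and 558 depleted and 18 and 21 enriched, in part by construction, since the null drops no extreme guide. The null of non-targeting guides gave 12742 and 11987 depleted and 4 and 4 enriched, and that of olfactory receptor guides 3438 and 3148 depleted and 32 and 48 enriched, because those guides lie above the library median. A threshold of 0.01 gave 665 and 655 depleted and 25 and 31 enriched, by its construction, and robust rank aggregation 59 and 67 enriched, where the cause was not tested. Of the main depleted genes, 763 and 726 were shared under robust rank aggregation, and all 565 and 558 without the farthest guide were among them.

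The difference between vectors had 0 calls in the main test; enriched counts were 3 with a pseudocount of 1 (AQR, NDC80 and SPI1), 1 with at least 100 counts (AQR) and 7 with the null of non-targeting guides, and depleted counts were 2 with that null and 2 from the day 7 libraries alone. At day 7 the 2 depleted calls became 0 with scaling on non-targeting guides, a pseudocount of 20, no count filter, at least 100 counts, no bins, robust rank aggregation, the farthest guide left out, a threshold of 0.01 and another draw, and 4 with the null of non-targeting guides; enriched calls went from 0 to 2 with a pseudocount of 1, 8 with the null of non-targeting guides and 6 with that of olfactory receptor guides. For the other changes in these comparisons the cause was not tested. Day 0 gave 0 under all run.

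Of 86 values of named genes, 79 kept their side of the threshold without the farthest guide and 86 with total counts, and 7 lost their call without that guide (ZNF845 and CSF2RA in YFP, DEFB104A, DEFB116 and 1 not named here in HMGA2, PNN and SEC22B at day 7). None turned. Of 81 list medians, 51 moved beyond their interval with control scaling, 6 with the median of guides, 5 with a pseudocount of 1, 2 with total counts and 0 with at least 100 counts. Control scaling turned the sign of 10 medians over time, the median of guides of 4, total counts of 3 (1 of them at -0.00) and a pseudocount of 1 of 1. Under control scaling, 10 of 153 enriched knockouts in YFP and 3 of 165 in HMGA2 had a mean below 0. Calls use ranks, so scaling moves few of them over time by construction. The planned restriction to gene guides was not run as a setting. Gene means used those guides alone, but size factors, abundance bins, ranks and random sets drew on all measured guides. No paired analysis was possible within a comparison because each group holds 1 library, and for that reason no library was left out; pairing the days over both vectors would average the vectors and was not run. YFP day 7 had the lowest depth, at a median of 50 counts per guide.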

Other observations

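The 6 gene groups below were chosen after seeing which knockouts were lowest, so their counts describe these libraries and are no independent test. Purine and thymidylate synthesis lost 15 of 22 members in YFP and 17 of 22 in HMGA2, around medians of -1.14 and -1.26, with PFAS at -2.11 ± 0.45 (n = 10) and -1.69 ± 0.41 and TYMS at -2.07 ± 0.31 (n = 13) and -1.90 ± 0.25. RNA polymerase I and ribosome assembly lost 20 of 31 with each vector, around -1.11 and -0.999, with IMP3 at -2.04 ± 0.34 (n = 10) and LAS1L at -2.02 ± 0.27 (n = 11) lowest in YFP and WDR75 at -1.93 ± 0.32 (n = 10) lowest in HMGA2. The proton pump of lysosomes and endosomes lost 8 of 13 with each vector, around -1.21 and -0.99, with ATP6V1A at -2.07 ± 0.41 (n = 10) and -1.91 ± 0.37. None of the 6 groups had a member past the threshold over all genes in the difference between vectors, and adjusted over the list alone 1 lower and 1 higher member of the RNA polymerase I and ribosome assembly group passed. That group had a median difference of 0.12, above the range of random lists at percentile 99.2. This decides nothing about HMGA2, since the group was assembled around knockouts that were lowest in YFP.

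Further groups were lost in part. Of the Integrator complex, which processes small nuclear RNAs, 4 of 16 were depleted in YFP and 5 of 16 in HMGA2, with INTS3 at -1.56 ± 0.29 and -2.28 ± 0.35 (n = 10). Of the damage clamp named 9-1-1 and the SMC5/6 complex, 4 of 12 were depleted with each vector, with RAD9A at -1.91 ± 0.35 and -2.15 ± 0.37 (n = 10). Cytoplasmic dynein and dynactin lost 5 of 16 with each vector, with the heavy chain DYNC1H1 at -1.80 ± 0.33 and -1.999 ± 0.30 (n = 10).

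Changes also followed position in the genome. Medians over time were lowest for genes of chromosome 19, at -0.19 in YFP and -0.18 in HMGA2, of chromosome 16, at -0.17 and -0.18, and of chromosome 17, at -0.17 in both. Windows of 25 neighbouring genes that passed with neither vector reached -0.50 and -0.49, below the lowest window of 100 shuffled orders, -0.33 and -0.34, in 268 and 226 of 16549 windows. The highest windows reached 0.24 and 0.25, above the highest shuffled ones, 0.18 and 0.17, in 155 and 193 windows. Windows overlap, so these are not counts of separate regions. Chromosome X was included, and its genes called with neither vector had medians of 0.15 in YFP and 0.14 in HMGA2. High windows may carry that shift. The 26 targets with date-like names had medians of -0.02 in YFP and -0.04 in HMGA2.

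The difference between vectors at day 0 correlated across genes, which are not independent replicates, with the difference of changes at a Pearson r of -0.296, and both contain the day 0 libraries.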
